A study of Homo sapiens with 10 samples.

How the data were processed

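Gene expression was measured with Affymetrix oligonucleotide arrays in a human cell line of chronic myeloid leukaemia (CML), a leukaemia driven by the BCR-ABL fusion tyrosine kinase, and in a subline of it that is resistant to cyclophosphamide. Cyclophosphamide is an alkylating drug whose activated forms are aldehydes that crosslink DNA. The labels do not give the name of the line or how resistance was raised. Per the labels' protocols, total RNA was copied into biotin-labelled cRNA, and each sample was hybridised to an array of its own with 1 colour. Groups and replicate numbers were taken from the sample titles: 5 arrays of sensitive cells and 5 of resistant cells. Nothing in the labels says that the 5 samples of a group came from separate cultures, so all p-values measure the spread between these samples, which may be technical.

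The deposited values are signals, an intensity on a linear scale per probe set and array, and the submitters' processing notes name MAS5, the Affymetrix algorithm that combines the perfect-match and mismatch probes of a probe set into 1 signal. Its version, its settings and the software for image analysis are not given in the sources used here. The values were checked for scale: the 2% trimmed mean was between 2501.33 and 2501.51 on all 10 arrays, so the authors' values had already been brought to a common level. The table holds 12625 probe sets. Of these, 67 are control probe sets and were left out of all tests, which leaves 12558. The values carry no calls of presence or absence that were used here. All 10 columns of the table were used.

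Probe sets were named through the platform annotation given with the data and updated by Entrez identifier to the gene table of assembly GRCh38.p14, which was used only for names, chromosomes and the order of genes. A single symbol was found for 10943 probe sets, several for 545 and none for 1070. Of the probe sets with 1 symbol, 10934 matched the gene table and 9 kept the annotation's own name. Probe sets with several symbols were tested but named no gene. In tests of gene lists and chromosomes, each of 8226 genes was represented by the probe set with the highest mean log2 signal, and 8203 of them were placed on a chromosome from 1 to 22 or X. Chromosome bands are not part of the gene table, so arms were not tested.

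Each array was scaled to the mean of the arrays' 2% trimmed means, which changed next to nothing here, and log2(signal + 114.8) was analysed. The pseudocount of 114.8 is the 20th percentile of all signals. Because of it, log2 differences understate the change of dim probe sets, and all folds derived from them are on the log2(signal + pseudocount) scale. Resistant minus sensitive differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over the 12558 probe sets. A probe set was called at an adjusted p under 0.05. All adjusted p-values given for genes are from this limma fit unless another test is named. The fit was tested on simulated data for this comparison, with 200 of 12558 probe sets changed. It recovered 8% of the changes of 0.58 on the log2 scale, 32% of those of 1, 82% of those of 2 and 100% of those of 4. It called 119 probe sets, 8 of them unchanged ones and 0 with the wrong sign. The simulation changed fewer probe sets than the 931 called in the data and drew independent noise. Its recovery rates therefore need not hold for the data.

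The background was set, after the data had been examined, from 32 control probe sets without a human target: the limit of an array was the 95th percentile of their signals, and it lay between 319.7 and 739.8. Where a gene was at or below the limit on all arrays of a group, its change is given as a bound ("at least N-fold"), the mean log2 signal of the bright group against the dim group's mean of, per array, the higher of the limit and the gene's own signal. A gene is called bright where it lay above the limit in at least 3 arrays of either group. The number of arrays limits the precision of every value.

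Before the data were examined, 35 gene lists were fixed: aldehyde dehydrogenases, glutathione genes, cytochrome P450 enzymes, redox genes, ATP-binding cassette (ABC) transporters, 3 groups of DNA repair genes, BCR-ABL signalling, kinases bound by tyrosine kinase inhibitors, apoptosis regulators, p53 targets, proliferation, interferon response, MHC class I and class II, 9 groups of cell type markers, adhesion molecules, cancer-testis antigens, heat shock, unfolded protein response, cholesterol synthesis, glycolysis, respiratory chain, ribosomal proteins, histones and retinoid genes. Lists and the 23 chromosomes were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment within each family. On simulated data, in which genes varied independently, camera called the 2 shifted sets among 58 and no other. That simulation cannot show how often camera calls unshifted sets of correlated genes. Values of a group are given as mean ± SD with n = 5. Single values were compared between groups with two-sided exact permutation tests, whose smallest possible p with 5 against 5 is 0.00794.

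The genes named in the text follow a rule fixed before the data were examined. It takes the 12 genes with the largest rise and the 12 with the largest fall among called probe sets with 1 symbol, complete separation of the groups and a mean signal in the higher group above the median of all signals, 656.8. It adds up to 4 called members with the smallest adjusted p of each list or chromosome described, and always the 10 genes ALDH1A1, ALDH3A1, BCR, ABL1, GSTP1, ABCB1, ABCC1, MGMT, LYN and BCL2. Any other gene named was chosen after its values were seen. The alternatives tried were the table as deposited, scaling to the median, quantile normalization, no pseudocount and pseudocounts at the 5th and 40th percentiles (31.4 and 398.7), the brighter part of the probe sets, limma's trend and robust options, array weights, the replicate number as a block, each array left out in turn, and, for sets, an estimated correlation, fry, and the mean over the probe sets of a gene. A filter at the negative control limit and list tests without chromosome 8 genes were added after the data had been examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.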

Results

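The data consisted of 10 oligonucleotide arrays, 5 of a CML cell line that is sensitive to cyclophosphamide and 5 of its resistant subline, each giving 1 signal for 12558 human probe sets. Both groups gave arrays of like quality. The share of probe sets above the negative control limit was 55.1% ± 2.59 in sensitive and 54.9% ± 4.34 in resistant arrays (SD, n = 5 each; two-sided exact permutation p = 0.921). The ratio of the 3' to the 5' GAPDH control signal, which lies near 1 where RNA is intact, was 0.876 ± 0.0374 and 0.847 ± 0.0715 (exact permutation p = 0.444). Across probe sets, which are not independent replicates, Pearson's r of log2 signals was 0.925 to 0.960 between sensitive arrays and 0.927 to 0.957 between resistant arrays. Between arrays of different groups it was 0.883 to 0.923.

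The comparison of the lines asked which transcripts differ in cells that withstand cyclophosphamide. In resistant cells the signal of ALDH1A1, a cytosolic aldehyde dehydrogenase that oxidises the aldehyde form of activated cyclophosphamide, was at least 151-fold higher, and the mitochondrial enzyme ALDH2 rose as well. The granule genes PRG2, PRTN3, CLC, RNASE2 and EPX of granulocyte precursors and eosinophils were at or near the negative control level in resistant cells, which had higher signals of the erythroid and platelet lineage genes KLF1 and ITGA2B. As lists, megakaryocytic genes were not called (camera adjusted p = 0.227) and erythroid genes were at the edge of the threshold (camera adjusted p = 0.0458). CA2, a member of the erythroid list, fell (log2 difference -5.24). Of 120 bright genes on the greater part of chromosome 8, 65 were called lower. In all, 931 of 12558 probe sets (7.41%) were called by limma at a Benjamini-Hochberg adjusted p under 0.05, 555 higher and 376 lower in resistant arrays. Of these, 704 differed by at least 2-fold, 454 upward and 250 downward. Of 8226 genes with a representative probe set, that probe set was called for 691, 406 higher and 285 lower. The groups did not overlap at all in 1067 of the 12558 probe sets (8.5%), where chance separates 0.794%, and 807 of these were called. Many changes were of an on or off kind. At or below the negative control limit on all sensitive arrays and above it on all resistant arrays were 95 called probe sets, and 42 were the reverse. Both groups were at or below the limit on all arrays for 26 called probe sets.

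ALDH1A1 showed the largest rise of the rule's genes, from a signal of 28.0 ± 15.5 in sensitive arrays, far under the limit, to 73953 ± 11710 in resistant arrays (SD, n = 5; adjusted p = 3.38e-11, limma). ALDH2 rose from 163 ± 208 to 14837 ± 1039 (log2 difference 5.97, SE 0.34, adjusted p = 4.74e-07), with 1 sensitive array above the limit. LGALS1, which encodes the secreted lectin galectin 1, rose by 5.46 on the log2 scale, and FSCN1, the actin bundling protein fascin, was at least 20.9-fold higher. MARCKS, a membrane protein that binds actin, was at least 9.49-fold higher. ANGPT1, a ligand of the receptor TEK, was at least 21.3-fold higher. The glycine receptor gene GLRB was at least 14.1-fold higher, the tyrosine kinase gene FYN at least 10.7-fold, the interferon-induced gene IFI44 at least 10.7-fold, RUNDC3B at least 12-fold and the collagen gene COL2A1 at least 8.96-fold. The lysosomal protease gene CTSH rose from 599 ± 224 to 21880 ± 4099. Their adjusted p-values in limma lay between 3.38e-11 and 5.22e-06.

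The 12 largest falls were led by PRG2, the eosinophil major basic protein, which fell from 146600 ± 59460, one of the brightest signals of sensitive cells, to 391 ± 269 (SD, n = 5; log2 difference -8.26, SE 0.39, adjusted p = 1.49e-07, limma). PRTN3, a neutrophil serine protease, was at least 56.9-fold lower. Its neighbour AZU1 was at least 22-fold lower. The eosinophil genes CLC and EPX were at least 22.4-fold and 19.3-fold lower, although both varied widely among sensitive arrays (32080 ± 45240 and 18420 ± 19530), and without sensitive replicate 5 the bound of CLC was 12.9-fold. RNASE2, an eosinophil ribonuclease, fell by 5.90 on the log2 scale. CEBPE, a transcription factor of late granulocyte maturation, was at least 21.6-fold lower, and MS4A3, a marker of granulocyte and monocyte progenitors, at least 44-fold lower. CST7, an inhibitor of lysosomal proteases, fell by 5.49 on the log2 scale. The 3 remaining genes have other functions. The cytokine gene IL32 was at least 58-fold lower, and COX7A2, a subunit of cytochrome c oxidase measured by 1 probe set, at least 28.2-fold lower. The carbonic anhydrase gene CA2 fell from 122110 ± 12930 to 3212 ± 835. The adjusted p-values lay between 5.57e-08 and 0.0016 in limma.

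**Figure D1:**
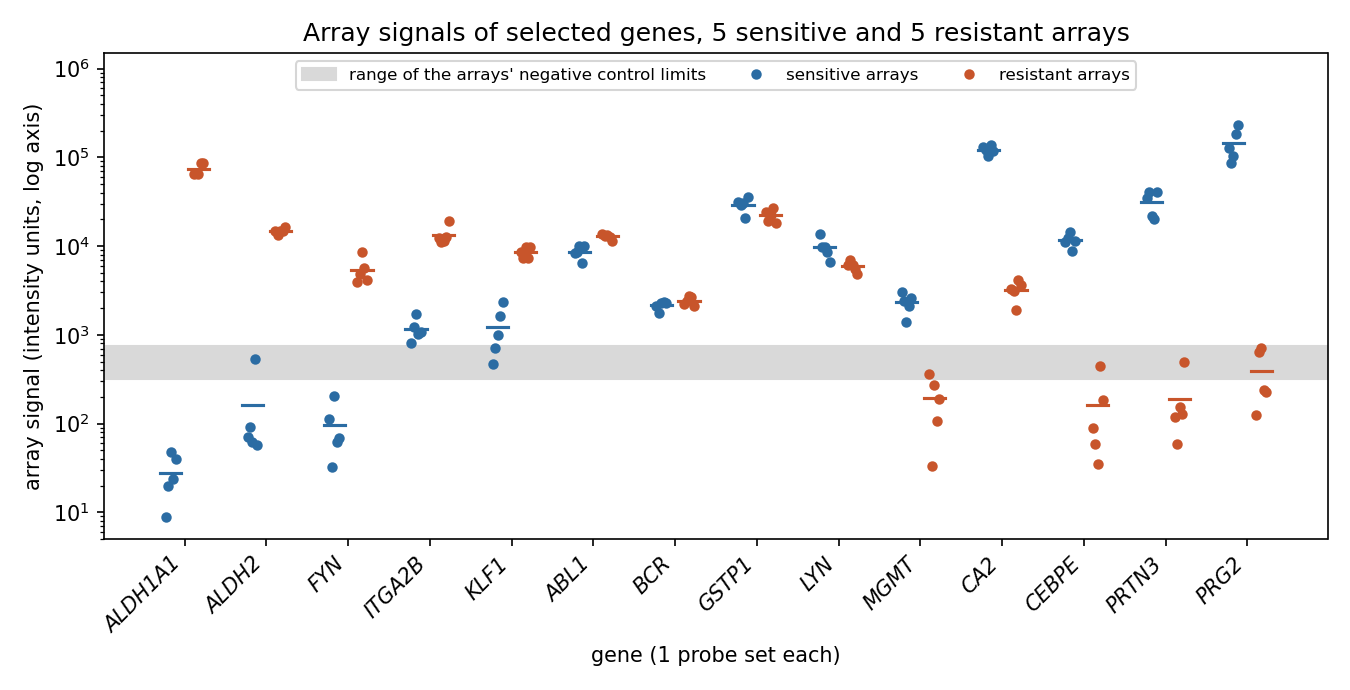
Array signals (intensity units, log axis) of 14 genes on the 5 sensitive and 5 resistant arrays; points are arrays, short lines are group means, and the grey band is the range of the arrays' negative control limits, 319.7 to 739.8. ALDH1A1 lies under the band in sensitive arrays at a mean of 28.0 and far above it in resistant arrays at 73953, PRG2 moves the other way from 146600 to 391, and the BCR signals of both groups overlap.

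Because aldehyde dehydrogenases and glutathione-dependent enzymes inactivate cyclophosphamide metabolites, both families had been chosen for a gene-by-gene account. Of 15 aldehyde dehydrogenase genes measured, 3 rose (ALDH1A1, ALDH2 and the folate enzyme ALDH1L1), 1 fell and 11 were not called; adjusted over the list alone, 4 rose and 1 fell. ALDH1L1 rose by 1.37 on the log2 scale, from 660 ± 297 to 1869 ± 716 (adjusted p = 0.0327, limma). Its call was lost under 9 of the alternatives, 6 of them with 1 array left out, at adjusted p-values of up to 0.0842. ALDH3B1 was at least 1.64-fold lower (adjusted p = 0.012). ALDH3A1, the other family member known to oxidise the drug's aldehyde, was 296 ± 167 in sensitive arrays, none of them above the limit, and 492 ± 231 in resistant arrays, of which 2 were above it (log2 difference 0.55, adjusted p = 0.527). As a list, aldehyde dehydrogenases were higher in camera (adjusted p = 0.00591; adjusted p = 0.307 with an estimated correlation). Of 17 glutathione genes, GSTO1 rose from 24309 ± 3153 to 48866 ± 4006 (log2 difference 1.01, adjusted p = 0.00209) and GPX1, a peroxidase, fell by 0.60 (adjusted p = 0.0372, and up to 0.0858 without any 1 of 9 arrays); adjusted over the list alone, 2 rose and 2 fell. The glutathione transferase gene GSTP1 was bright in both groups and not called, with log2 differences of -0.40 and -0.50 in its 2 probe sets (adjusted p = 0.331 and 0.156). The 17 measured glutathione genes did not shift as a list (camera adjusted p = 0.953). Of the 27 glutathione genes listed, 10 were not measured, 7 of them covered only by probe sets with several symbols. The account of this family is therefore incomplete.

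Other genes of drug handling changed singly. None of 20 cytochrome P450 genes was called by limma, with 1 higher and 2 lower at an unadjusted p under 0.05. A further 8 listed P450 genes were not measured, 5 of them covered only by probe sets with several symbols. Of 32 ABC transporter genes, the efflux pump gene ABCG2 was at least 2.73-fold higher (adjusted p = 0.0025) and ABCC10 fell by 0.75 (adjusted p = 0.017, but 0.274 for the mean of its probe sets), also adjusted over the list alone. ABCC10 was called in 1 of its 3 probe sets. ABCB1, which encodes P-glycoprotein, was not above the limit on any array in its 2 probe sets. The best measured of 4 probe sets of ABCC1 was 987 ± 164 in sensitive and 1503 ± 272 in resistant arrays (log2 difference 0.55, adjusted p = 0.11). Among 32 redox genes 2 rose and 4 fell, or 3 and 5 adjusted over the list alone. PRDX2, a peroxiredoxin, had a log2 difference of -1.57, and PGD and ME1, enzymes that supply NADPH, had -0.91 and -2.22 (adjusted p = 7.14e-05, 0.00459 and 0.00229, limma). ME1 was called in 1 of its 3 probe sets. CBR3, a carbonyl reductase, was at least 1.24-fold higher. The camera tests of these 3 lists gave adjusted p-values of 0.869, 0.849 and 0.845, in the order P450 enzymes, transporters, redox genes.

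The lists of DNA repair genes, which act on the lesions that the drug leaves, held few called genes. In the list of crosslink repair and homologous recombination 1 of 27 genes fell, NBN of the MRE11 complex, by 0.72 on the log2 scale (adjusted p = 0.0464, limma, and up to 0.119 without any 1 of 9 arrays); adjusted over the list alone, 0 did, with 2 higher and 3 lower at an unadjusted p under 0.05. In excision repair and direct reversal 1 of 31 fell. It was MGMT, the methyltransferase that removes alkyl groups from guanine, which fell from 2328 ± 618 to 192 ± 129 (log2 difference -3.07, SE 0.32, adjusted p = 6.79e-05) and by 2.23 in its other probe set. In mismatch repair and end joining 1 of 10 fell, PRKDC, the catalytic subunit of DNA-dependent protein kinase, from 24594 ± 2483 to 12582 ± 1437 (adjusted p = 0.00292). Adjusted over the list alone, the last 2 counts were the same. NBN and PRKDC lie on the lowered part of chromosome 8. None of the 3 lists shifted in camera (adjusted p = 0.435, 0.675 and 0.593).

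BCR-ABL expression was a stated question of the design. The arrays carry probe sets for both partner genes and none known to be specific for the fusion. The parts of each gene that the probe sets cover are not given in the sources used here. It is therefore not known which signals include fused transcripts beside normal ones. Some but not all ABL1 probe sets were called higher in resistant cells. Of 6 ABL1 probe sets, 3 were called, with log2 differences of 0.71 (7352 ± 733 to 12040 ± 749, adjusted p = 0.014, limma), 0.80 (2820 ± 510 to 4975 ± 834, adjusted p = 0.0239) and 1.10 (409 ± 210 to 965 ± 251, adjusted p = 0.0382). The brightest, at 8656 ± 1496 and 12856 ± 866, was not called (log2 difference 0.58, adjusted p = 0.0738), although in an exact permutation test its groups did not overlap (p = 0.00794, or 0.0317 adjusted over the 12 probe sets of both genes). By exact permutation with that adjustment 4 ABL1 probe sets passed. The other 2, above the limit on all sensitive arrays, had log2 differences of -0.17 (822.7 ± 243 and 741.7 ± 329, adjusted p = 0.823) and 0.15 (1607 ± 408 and 1796 ± 450, adjusted p = 0.819). None of the 6 BCR probe sets was called by limma, 0 reached an unadjusted p under 0.05, and by exact permutation the lowest p was 0.159. The brightest BCR probe set was 2171 ± 246 and 2425 ± 259 (log2 difference 0.15, SE 0.16). The ABL1 calls were marginal. With arrays scaled to a common median 0 of the 12 were called, at log2 differences of 0.58, 0.67 and 0.99 for the 3 ABL1 probe sets above (adjusted p = 0.0988, 0.168 and 0.072), and without sensitive replicate 3 or without resistant replicate 2 there was 1.

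Several signalling genes known to act with or below the fusion kinase rose. Of 32 genes of BCR-ABL signalling 7 rose and 2 fell, or 11 and 3 adjusted over the list alone, and the list did not pass in camera (adjusted p = 0.134) and passed with fry, which does not compare it with other genes (adjusted p = 0.000161). The cyclin gene CCND2 was at least 6.2-fold higher. DUSP6, a phosphatase induced by and acting on ERK, rose from 3594 ± 1230 to 17164 ± 3664 (log2 difference 2.26, adjusted p = 0.000149), STAT5A rose by 1.48 (adjusted p = 0.000706) and SOCS2, a STAT5 target, by 1.33 (adjusted p = 0.00079). Of 19 kinases bound by tyrosine kinase inhibitors 4 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.461; 0.00703 with fry). FYN rose from 95.5 ± 65.9 to 5401 ± 1842, the ephrin receptor gene EPHB4 was at least 2.64-fold higher, FLT3 was called higher with 1 resistant array and 0 sensitive arrays above the limit, and SYK fell by 1.86 (adjusted p = 8.82e-05). FYN was called in 2 of its 4 probe sets and FLT3 in 1 of 2. LYN, a SRC family kinase gene on the lowered part of chromosome 8, had log2 differences of -0.66, -0.58 and -0.53 in its 3 probe sets, none of them called (lowest adjusted p = 0.0895).

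Of 34 apoptosis regulators 2 rose and 3 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.869). The survival gene BCL2L1 rose by 1.11 (adjusted p = 0.0047, limma) and the death ligand gene TNFSF10 by 2.32 (adjusted p = 0.00209). BCL2L1 was called in 1 of its 2 probe sets. BIK, a promoter of apoptosis, was at least 3.43-fold lower and CASP1 at least 2.04-fold lower. BCL2 was not called in any of its 5 probe sets, and the brightest was 2248 ± 512 and 3083 ± 549 (log2 difference 0.45, adjusted p = 0.285). Of 18 p53 targets, GDF15 and CCNG1 rose, by 1.43 and 1.09 (adjusted p = 0.0449 and 0.0452), also adjusted over the list alone, and 0 fell (camera adjusted p = 0.134). Both calls were lost without any 1 of 8 arrays, with adjusted p-values of up to 0.115 for GDF15 and 0.107 for CCNG1.

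Several granulocytic markers fell, and several erythroid and stem cell markers rose. Of 29 granulocytic genes, 11 fell and 1 rose, also adjusted over the list alone, and 17 were not called. The falls included PRG2, PRTN3, CEBPE and RNASE2, and the gene that rose was LYZ, lysozyme, which was at least 2.55-fold higher. The list was lower in camera (adjusted p = 1.24e-05; adjusted p = 0.0489 with an estimated correlation). Its median was -0.12, and 15 of its genes were bright in at least 1 group. Of 22 erythroid genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone. KLF1, the erythroid transcription factor, rose from 1222 ± 758 to 8548 ± 1224 (adjusted p = 0.000206), TAL1 rose by 1.98 and BLVRB by 1.39, whereas CA2 fell. The list was at the edge of the threshold (camera adjusted p = 0.0458; adjusted p = 0.307 with an estimated correlation) and was lost under 13 of 25 alternatives, among them any 1 of 6 arrays left out, at adjusted p-values of up to 0.0863, although without chromosome 8 genes it was 0.00127. Of 19 stem and progenitor genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0222; adjusted p = 0.307 with an estimated correlation, and up to 0.083 without any 1 of 4 arrays), a call lost under 8 of 25 alternatives. MECOM was at least 5.88-fold higher and TEK, the angiopoietin receptor, at least 3.09-fold higher, with FLT3 and TAL1 shared with other lists. MECOM was called in 2 of its 4 probe sets and TEK in 1 of 2.

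Markers of other blood lineages gave no list past the threshold in camera. Of 14 megakaryocytic genes ITGA2B, the platelet integrin chain, rose from 1169 ± 337 to 13396 ± 3366 (adjusted p = 1.81e-06, limma) and PDGFA rose by 0.93, a call lost under 13 alternatives (adjusted p of up to 0.462), with 0 falls, or 3 rises adjusted over the list alone (camera adjusted p = 0.227; 0.00398 with fry). PDGFA was called in 1 of its 2 probe sets. Of 26 monocytic genes 3 rose and 0 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.458). FCGR2A rose by 1.30 and AIF1 by 0.99, calls that were lost under 7 and 9 alternatives (adjusted p of up to 0.0807 and 0.092), and TLR2 was called with 2 resistant arrays and 0 sensitive arrays above the limit. FCGR2A was called in 1 of its 2 probe sets and AIF1 in 1 of 3. In 17 B lymphoid genes 1 rose (RAG2) and 1 fell (CD24), or 2 and 1 adjusted over the list alone. In 25 T and NK genes CD8B rose and in 8 mast cell genes HPGDS rose and FCER1A, at or below the limit on all arrays, was called lower, also adjusted over the list alone. These 3 lists had camera adjusted p-values of 0.407, 0.305 and 0.869. In 22 fibroblast and epithelial genes SPARC was at least 7.02-fold higher and LUM at least 2.3-fold lower, also adjusted over the list alone (camera adjusted p = 0.845).

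**Figure D2:**
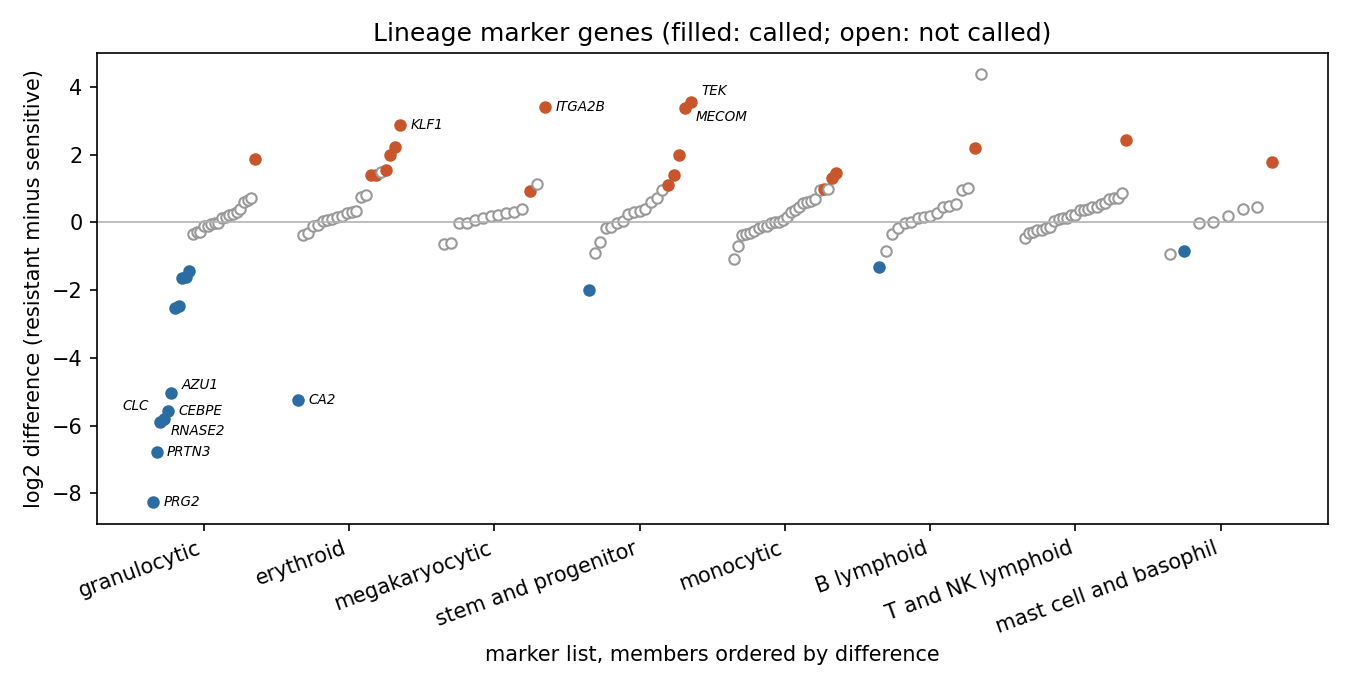
Log2 differences (resistant minus sensitive) of the measured members of 8 lineage marker lists, 1 point per gene; filled points are called by limma and open points are not. The granulocytic list carries the deepest falls, down to -8.26 for PRG2, while ITGA2B at 3.40 and KLF1 at 2.87 lie among the called rises; the open point at 4.36 in the B lymphoid list is IGLL1, which varied too widely to be called.

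Interferon-response genes were higher as a list, though not all of them. Of 34 genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00719; adjusted p = 0.0844 with an estimated correlation, and 0.0568 in the brighter part of the probe sets). IFI44 rose from 133 ± 141 to 5231 ± 661, IFIT3 from 671 ± 348 to 2945 ± 1075 (adjusted p = 0.00141, limma), and IFI16 was at least 1.46-fold higher. The antiviral gene MX2 went the other way and was at least 5.98-fold lower (adjusted p = 3.02e-06). Of 13 MHC class II genes HLA-DMA was at least 1.94-fold higher and HLA-DPB1 was called higher while at or below the limit on all arrays, also adjusted over the list alone, a call lost under 13 alternatives at adjusted p-values of up to 0.876. HLA-DPB1 was called in 1 of its 2 probe sets. Of 13 MHC class I genes HLA-E rose by 1.67 on the log2 scale, or 1 rise and 2 falls adjusted over the list alone. Their camera adjusted p-values were 0.259 and 0.144. Of 37 adhesion genes 3 rose and 4 fell, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.996). ICAM3 was at least 8.38-fold lower and the integrin gene ITGA4 fell by 1.79, whereas ICAM2 rose by 2.26 and ITGA5, the fibronectin receptor chain, by 1.95.

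The lists of cholesterol synthesis, glycolysis and respiratory chain genes were lower in camera at the preset correlation, and none of these calls held with an estimated one (adjusted p = 0.307, 0.55 and 0.55 with an estimated correlation). Of 18 cholesterol synthesis genes 5 fell and 0 rose, or 10 and 1 adjusted over the list alone. They included EBP, which fell from 42796 ± 8232 to 11389 ± 2904 (log2 difference -1.91, adjusted p = 0.000147, limma), ACAT2 (log2 difference -1.24), SQLE (-1.38) and SC5D (-0.71, a call lost under 3 alternatives at adjusted p-values of up to 0.0597). The list had the lowest p of the 35 lists in camera (adjusted p = 5.36e-06). Of 24 genes of glycolysis and hypoxia 4 fell and 1 rose, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0222; 0.0775 after quantile normalization, 0.115 with fry and 0.117 without sensitive replicate 1). The log2 differences were -2.01 for BNIP3, -1.04 for P4HA1, -0.72 for GPI and 2.92 for the enolase gene ENO2. The calls of P4HA1 and GPI were lost without any 1 of 6 and any 1 of 8 arrays, at adjusted p-values of up to 0.0828 and 0.0943. Of 44 respiratory chain genes 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0105; 0.146 after quantile normalization). They were COX7A2 and, on the lowered part of chromosome 8, CYC1 and UQCRB, with log2 differences of -0.94 and -1.28. SQLE lies on that part as well. Of 20 retinoid genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.408; 5.14e-05 with fry and 0.0457 with the negative control filter). Beside ALDH1A1, which also makes retinoic acid, the retinal reductase gene DHRS3 was at least 3.7-fold higher and CD38 at least 1.54-fold higher, and the receptor gene RXRA fell by 2.31.

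Lists of general cell functions held few called genes. None of 47 ribosomal protein genes was called by limma, with 1 lower at an unadjusted p under 0.05. Of 42 proliferation genes MCM4 and CCNE2 fell, both on the lowered part of chromosome 8. Of 25 histone genes 2 fell (H1-10 and H1-2, the second above the limit on 1 array), of 23 heat shock genes 1 fell (HSPA1L, at or below the limit on all arrays), and of 17 cancer-testis genes 1 rose (PRAME). Of 26 genes of the unfolded protein response WARS1 rose and SLC7A5 fell. Adjusted over the list alone, these counts were the same, except that 2 genes of the unfolded protein response rose. The camera adjusted p-values were 0.869 for ribosomal proteins, 0.845 for proliferation, 0.0557 for histones (called under 4 alternatives), 0.171 for heat shock, 0.996 for cancer-testis antigens and 0.869 for the unfolded protein response. In 9 lists, 0 of them called, the median, the mean and the direction of the camera test differed in sign. Not measured were 33 further listed histone genes, 27 of them covered only by probe sets with several symbols. The same holds for 32 further ribosomal protein genes, 18 of them so covered.

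Chromosome 8 was the 1 chromosome of 23 that camera called. Of its 298 measured genes 69 were lower and 13 higher in resistant cells (adjusted p = 3.07e-07; adjusted p = 0.04 with an estimated correlation), and the next lowest adjusted p of a chromosome was 0.837. Among its 188 bright genes 78.2% lay below the median of the other chromosomes. The median of those genes on each array, relative to the other chromosomes and to the mean of all arrays, was 0.26 ± 0.05 in sensitive and -0.27 ± 0.05 in resistant arrays on the log2 scale (SD, n = 5; two-sided exact permutation p = 0.00794, the smallest possible). Chromosome 8 had been picked out of the 23 on these same arrays, so this p was close to fixed in advance and is not separate evidence. The shift was not spread over the whole chromosome. The best single change point in gene order, sought after the data had been examined, fell between SLC20A2 and CHRNA6. The 68 bright genes before it had a median difference from the other chromosomes of -0.04 (95% bootstrap interval -0.15 to 0.07). The 120 genes after it had -0.86 (-0.99 to -0.76), or 0.551 of the sensitive level. Of these 120, 65 were called lower, 5 higher and 50 not at all. CA2 fell furthest, and ANGPT1 rose against the trend. DLC1 and RBPMS, which were at least 7.07-fold and 6.66-fold higher, lie before the change point.

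**Figure D3:**
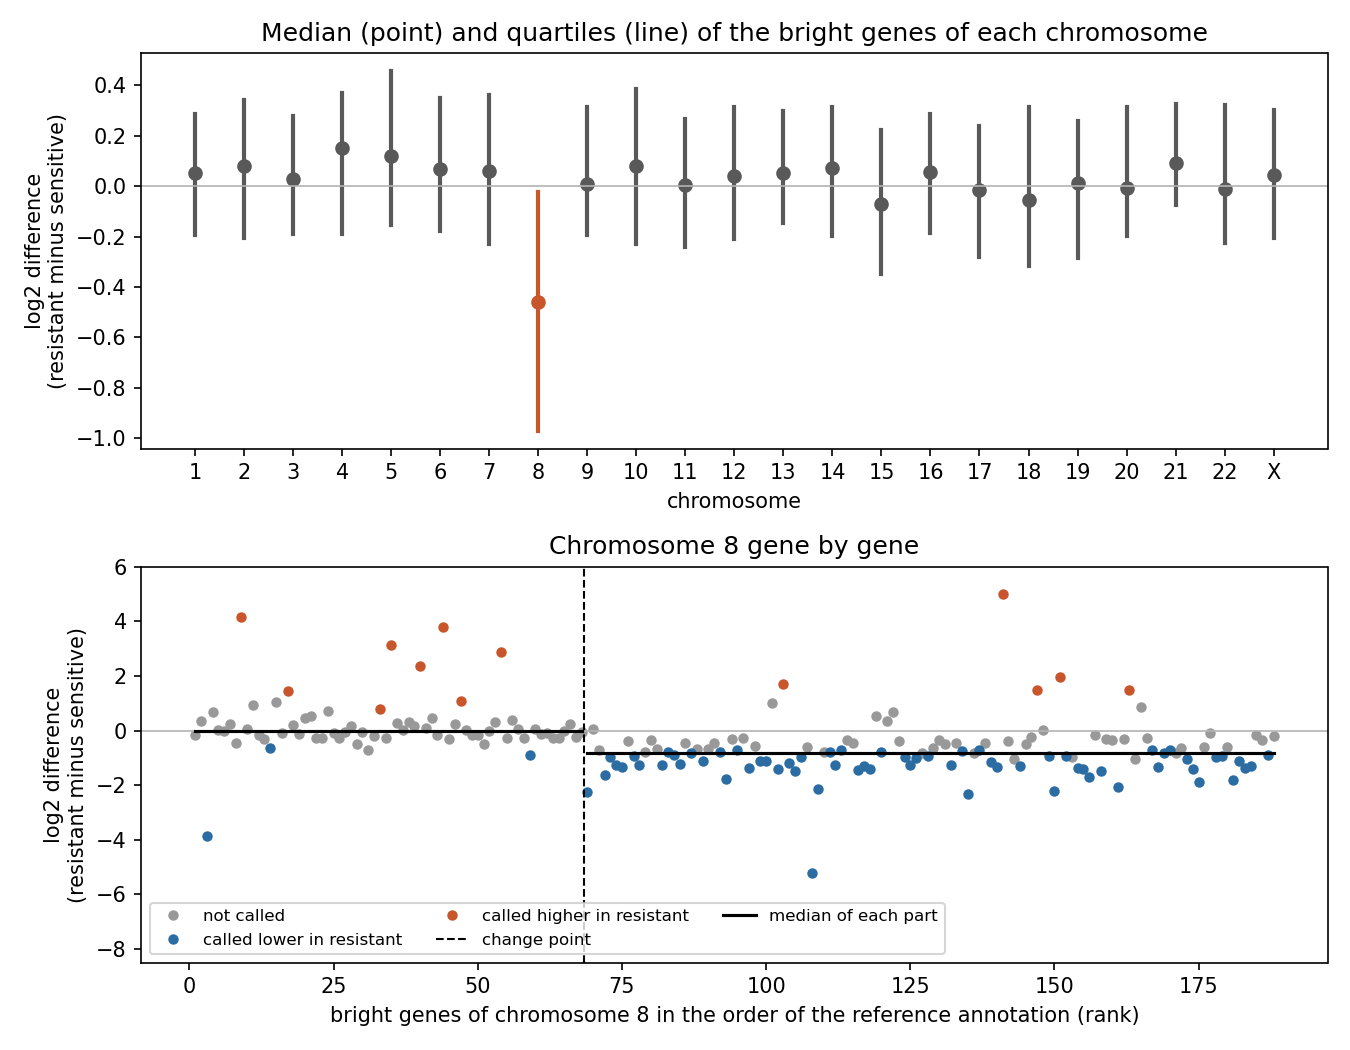
Upper panel, the median (point) and quartiles (line) of the log2 differences (resistant minus sensitive) of bright genes on each chromosome; lower panel, the 188 bright genes of chromosome 8 in gene order, 1 point per gene, with the change point (dashed line) and the median of each part (black lines). The chromosome 8 median is -0.46 while those of the other chromosomes lie between -0.07 and 0.15, and 90.8% of the genes after the change point lie below the median of the other chromosomes.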

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

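Within each group of 5 arrays, single arrays that stood far from the other 4 were sought for the named genes with Dixon's test, in 184 combinations of a gene and a group. It found 14, where chance gives about 1 in 20, or 9.2. In resistant replicate 3, CTSH was low at 14720 (the other resistant arrays 22220 to 24580) and IFI44 was low at 4119 (5318 to 5880), whereas IFIT3 was high at 4833 (2177 to 2746) and MECOM was high at 4369 (2406 to 2736). In resistant replicate 5, BLVRB was high at 6636 (4477 to 4822) and ITGA2B at 19300 (11190 to 12720). PRKDC was low in resistant replicate 4 at 10110 (12630 to 13600). In sensitive replicate 4, ALDH2 was high at 535 (56.8 to 92.5) and SOCS2 at 3114 (1837 to 2031). None of these values reached the range of the other group for CTSH, IFI44, IFIT3, MECOM, BLVRB, ITGA2B, PRKDC, ALDH2 or SOCS2.

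The remaining outlying values lay at or near the background. ME1 was 347.5 in resistant replicate 1 (34.4 to 71.2 in the other resistant arrays), above that array's limit of 319.7, and the others were under their arrays' limits. ICAM3 was 422 in resistant replicate 2 (29.2 to 86.9). CBR3 was 330.4 in sensitive replicate 5 (41.1 to 89.8), CD38 was 216.1 in sensitive replicate 1 (30.5 to 50.1), and HLA-DPB1 was 84.1 in sensitive replicate 5 (123.6 to 141.1).

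Among the control probe sets, which entered no comparison, AFFX-TrpnX-M_at, a control for a bacterial transcript, had a mean of 50.18 in resistant arrays and 17 to 30.2 on the sensitive arrays. All of these values lie under the lowest negative control limit of 319.7.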

How the results depend on the processing

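The filter at the negative control limit and the list tests without chromosome 8 genes were chosen after the data had been examined. All 24 genes of the largest changes were called under each alternative that applies to single genes. They had been chosen from these same data for large, fully separated differences, so this outcome was close to fixed in advance. The number of called probe sets stayed between 750 and 1169 under other settings and between 691 and 860 without any 1 array, against 931, and scaling to the median moved the share of higher calls from 59.6% to 50.9%. The deposited table without further scaling gave the same calls, but it differs from the main setting in next to nothing and so tests nothing. Chromosome 8 and the granulocytic list were called under all alternatives, at adjusted p-values of up to 0.04 and 0.0489. Results that changed are given next, and the cause was not tested. Of 12 BCR and ABL1 probe sets, 0 were called with median scaling and 1 to 3 without any 1 array, the lowest without sensitive replicate 3 or resistant replicate 2. Quantile normalization left 5 lists called in place of 8, with adjusted p-values of 0.146 for the respiratory chain, 0.0775 for glycolysis and 0.0542 for erythroid genes. Without a pseudocount stem and progenitor genes were at 0.0802 and erythroid genes at 0.0554, and with the pseudocount at the 5th percentile at 0.0566 and 0.0550. In the brighter part of the probe sets interferon genes were at 0.0568 and erythroid genes at 0.0604, and with the negative control filter interferon genes were at 0.0531. The mean over the probe sets of a gene gave 0.0533 for erythroid genes. With fry, which does not compare a list with other genes, glycolysis was at 0.115 and erythroid genes at 0.0838, and 2 chromosomes were called, 8 and 4. An estimated correlation left 1 list called, the granulocytic one, with 0.307 for cholesterol, aldehyde dehydrogenase, stem and progenitor and erythroid genes, 0.0844 for interferon genes and 0.55 for the respiratory chain and glycolysis. Without any 1 array, the adjusted p ran from 0.00741 to 0.083 for stem and progenitor genes (above 0.05 without sensitive replicate 5 or resistant replicate 1, 4 or 5), from 0.00592 to 0.117 for glycolysis (without sensitive replicate 1) and from 0.017 to 0.0863 for erythroid genes (without sensitive replicate 2 or 5 or resistant replicate 1, 3, 4 or 5). Lists also gained calls: with fry 10 were called, among them BCR-ABL signalling (0.000161), retinoid genes (5.14e-05), megakaryocytic genes (0.00398) and kinases bound by inhibitors (0.00703). Without sensitive replicate 4 there were 10, with p53 targets (0.0423) and heat shock (0.0256), and without chromosome 8 genes there were 9, with histones at 0.0346 and erythroid genes at 0.00127. Histones were also called without sensitive replicate 2 or 3 or resistant replicate 5, and retinoid genes with the negative control filter (0.0457). Over the alternatives with camera the lowest adjusted p was 3.57e-07 for cholesterol, 0.000725 for aldehyde dehydrogenases, 0.00369 for interferon, 0.00261 for the respiratory chain and 0.00741 for stem and progenitor genes. For single genes named in the text, 138 values out of 2206 lost their call and 13 gained one, and 0 changed sign past the threshold. Calls were lost under 13 alternatives for PDGFA and HLA-DPB1, 12 for NBN, GPI and the dimmest called ABL1 probe set, 11 for GDF15 and CCNG1, 10 for GPX1, 9 for ALDH1L1 and AIF1, 7 for FCGR2A and P4HA1, 3 for SC5D, 2 for ABCC10, and 5 and 2 for the other called ABL1 probe sets. A call was gained under 6 for LYN, 5 for ABL1 and 2 for ABCC1.

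The replicate numbers were not taken to pair the arrays. The correlations of the deviations of same-numbered arrays from their group means were 0.038, 0.022, 0.123, 0.009 and 0.041, and 4 of the 10 arrays correlated best with their own number in the other group. With the replicate number as a block, 794 probe sets were called, of which 741 were among the 931. The block gave 1 called BCR or ABL1 probe set and an adjusted p of 0.0737 for stem and progenitor genes, and it changed the call of no other list or chromosome.

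Signal over background limits these results: 55.1% of probe sets on the sensitive and 54.9% on the resistant arrays lay above the negative control limit, and below it changes cannot be measured.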

Other observations

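The genes named in the first paragraphs, on HOX genes and other families, were chosen after their values were seen, and so were the tests of the part of chromosome 8 after the change point, of S100A8, S100A9 and S100A12, and of COX7A2 and RRAGA. Of 18 measured HOX genes, which set cell identity along the body axis and in blood progenitors, 6 rose and 0 fell in limma, and 12 were not called. HOXC6 was at least 5.07-fold higher (signals of 210 and 2519, adjusted p = 8.91e-05) and HOXB5 at least 2.46-fold higher, HOXB7 rose by 2.23, HOXC5 by 1.97, HOXB6 by 1.22 and HOXB2 by 1.11. The other 2 probe sets of HOXC6 were not called, and 10 of the 18 genes were not above the limit in 3 arrays of either group. The family was looked at because of these values, so no test of it as a family is given.

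Genes of other families stood out as well. ID1, an inhibitor of differentiation, rose from 6899 to 61360, the growth factor gene MDK from 2265 to 20890, and the calcium-binding protein gene S100A4 from 548 to 5935. Both chains of soluble guanylate cyclase rose, GUCY1B1 at least 4.14-fold and GUCY1A1 at least 1.31-fold. In the other direction, the chemokine receptor gene CCR8 was at least 8.66-fold lower and CXCR4 at least 3.71-fold lower, ALOX5AP, which activates leukotriene synthesis, fell by 4.11 on the log2 scale, and the tissue factor gene F3 was at least 2.87-fold lower. GBE1, the glycogen branching enzyme, fell from 35310 to 5276, and P4HB, a disulfide isomerase, from 71180 to 18940. Adjusted p-values of these genes in limma lay between 1.4e-06 and 0.00409. MYC, on the lowered part of chromosome 8, was 37810 in sensitive and 34060 in resistant arrays (log2 difference -0.17, adjusted p = 0.717).

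The difference between the lines as a whole was set against other groupings of the same arrays. Of 100 splits drawn from the 126 possible ones, 1 gave as many calls as the real split, which was that split itself with 931, and the highest of the others gave 4. The count is thus beyond what the other drawn groupings of these arrays gave, each of which mixes the 2 lines. Because the samples of a group may be technical repeats, the splits do not exclude chance differences between cultures. Whether the 2 lines differ through selection by the drug, through time in separate culture or in origin was not tested.

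Chromosome 8 genes were lower in resistant cells. A few strongly changed genes are not the source, since the 107 bright genes of the chromosome that were not called were also shifted, by -0.263 (95% bootstrap interval -0.313 to -0.16), nor is signal level, since 0% of 10000 random lists matched on mean signal had a median as low, the lowest being -0.05 against -0.26. Fewer copies of the whole chromosome would lower all of it: 9 of 10 blocks in gene order lay below the other chromosomes, which met the bound set beforehand, but that bound ignored spread, and the first 3 blocks, from ERICH1 to FGFR1, had intervals of -0.20 to 0.33, -0.30 to 0.26 and -0.19 to 0.36, which lay above those of the last 6 blocks, while that of block 4, across the change point, reached from -0.95 to -0.13. After the change point the median was -0.861 (interval -0.987 to -0.755), between the -0.585 of 2 copies against 3 and the -1 of 1 copy against 2. The interval takes genes as independent and the arrays and change point as fixed, and the pseudocount understates changes. It therefore does not settle whether either copy ratio holds. The change point was placed where the shift is largest and DNA was not measured, so fewer copies of that part and a regulatory change across it cannot be told apart.

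Several granulocytic markers fell in resistant cells. Of the abundant neutrophil transcripts S100A8, S100A9 and S100A12, 0 lay above the limit in 3 or more sensitive arrays, although S100A8 did on 1. These values argue against mature neutrophils as a large part of the sensitive cultures. No neutrophil sample shows that these probe sets detect them, so a small share of neutrophils is not excluded. For maturing granulocytes in general too few values bear on the source of the signals. Above the limit in 3 or more sensitive arrays were 2 of 14 mature markers. They were CSF3R, which was at least 1.38-fold lower, and CXCR2, with a log2 difference of 0.14 (adjusted p = 0.905, limma). Loss of a minority of mature granulocytes and lower expression in all cells therefore cannot be told apart. CLC was 41628 and 107507 on sensitive replicates 4 and 5 and 3590 to 3860 on the other 3, EPX was 40734 and 38859 against 3585 to 4885, PRG2 was 182061 and 231416 against 87498 to 128799, and MS4A3 was 39685 and 32805 against 16468 to 18673. The eosinophil gene RNASE2 did not follow, with 11515 and 29590 against 15026 to 39994, and CEBPE stayed between 8887 and 14359.

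Called genes above the limit on all arrays of 1 line and at or below it on all arrays of the other numbered 105. Of these, 70 were higher and 35 lower in resistant cells. Probe sets that fail in 1 line are not the source where a gene has another bright probe set, since 93.8% of those, 15 of 16, were called in the same direction. Joint loss or gain of neighbouring genes could not be decided: 19 neighbours were called the same way, as many as the 95th percentile of random draws, among them AZU1, PRTN3, ELANE and CFD. For COX7A2 and RRAGA, at least 28.2-fold and 8.63-fold lower, the 4 nearest bright neighbours (EEF1A1, PHIP, PSIP1 and PLIN2) differed by at most 0.61. These values argue against complete loss of a segment that reached these neighbours. DNA was not measured, so loss of some copies of such a segment is not excluded. Dim or unmeasured genes may lie closer, so loss of a shorter segment was not tested. COX7A2 and RRAGA have 1 probe set each, so a sequence change under the probes or a loss within the gene may be the cause as well as loss of the transcript, and these cannot be told apart.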
